A study of Mus musculus with 4 samples.

How the data were processed

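Cells of the back skin dermis of mice at 2, 12 and 18 months of age, sorted for hair follicle mesenchyme, were profiled by 10x 3' single-cell RNA sequencing in 4 libraries, with chemistry version 2 (2 and 18 months) or 3 (2 and 12 months). Each library was made from 10000 sorted cells, 5000 per gate. Per the labels each sample had n = 2 mice. The chemistry and reporter of each library were taken from the sample characteristics; the protocol text of the version 3 samples still names the YFP reporter. The deposited values are whole-number UMI counts per gene and cell barcode that the authors made with STAR (no version given), Cell Ranger 2.0.1 and Seurat 2.1.0, which the processing notes name without roles, on builds mm10 and GRCm38.p5. The headers of the version 3 matrices name software version 3.0.1 instead. The settings of cell calling are not stated, and the files hold called barcodes only, so the background of empty droplets could not be measured. Each file holds 27999 genes, including an added eYFP entry. Genes are named by the symbols in the files.

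The 4 files held 17130 barcodes and 171343515 UMIs. Barcodes with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept. This removed 177 and 221 barcodes in version 2 (2 and 18 months) and 1468 and 1387 in version 3 (2 and 12 months), and the mitochondrial limit removed 9.29%, 7.99%, 19.2% and 23.8% of barcodes. The 3% of cells with the highest Scrublet doublet score were removed in each library, after the authors' estimate of 3% doublets. Scrublet's own threshold called 9, 10, 5 and 2 cells, too few for these library sizes to be believed, so it was not used and doublets remain possible. This left 13460 cells.

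The 4 libraries were clustered together in scanpy 1.11.5 (Python 3.11.15, igraph 0.11.9, scikit-learn 1.9.0) from 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 0.5. Each gene was scaled within its library, with no further integration, and sex-linked, mitochondrial, ribosomal, immediate early and heat shock genes and eYFP were left out of this step. The 22 clusters were named from 19 marker lists written before the data were examined. A name needed at least 3 markers of its list among the cluster's top 100 genes, each at least 1.5-fold higher and in at least 20% of cells, in libraries with at least 10 cells of the cluster. Cycling clusters were judged by their top 10 genes. The resolution (first 1, then 0.5), the use of folds within libraries, the pooling of 3 fibroblast and of 2 endothelial lists and the rule for cycling clusters were set after marker genes and cell counts per library of the clusters had been seen, and before expression was compared between ages. Class names carry the ending -like because they rest on markers alone. Clusters differ between libraries, so cells of a class were summed over its clusters.

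Shares of cells have exact Clopper-Pearson intervals and ratios of CPM of summed UMIs have exact conditional Poisson intervals, both at 95% and both for counting error only (scipy 1.17.1). A ratio against 0 UMIs was bounded with 3 UMIs in that library. Medians of list members used a prior count of 0.5 and were placed among 10000 random lists drawn from 20 bins of expression. Within a pair no test of genes was possible, because each age and chemistry has 1 library. The median log2 ratio over all genes was 0.124 at 18 and -0.106 at 12 months over all kept cells, 0.361 at 18 months in keratinocyte-like cells, -0.278 and -0.298 in macrophage and dendritic-like cells and -0.117 at 12 months in dermal papilla-like cells. Ratios are given without this shift. Rescaled by the trimmed mean of M-values (TMM) within the pair, 3 of 360 ratios of genes chosen by the rule changed sign, those of Ccl2, Ccl4 and Ccl7 at 12 months in macrophage and dendritic-like cells. The shifts are too small to turn a ratio of 2-fold or more.

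The 12-month and 18-month libraries were tested against both 2-month libraries on UMIs summed per library, over all kept cells and for each class with at least 50 cells in every library. The test was edgeR 4.0.16's two-sided quasi-likelihood F-test (R 4.3.3) with TMM, its default filter on low counts and chemistry as a covariate, which left 1 residual degree of freedom, with Benjamini-Hochberg adjustment at 0.05. The SE given is the absolute log2 fold divided by the square root of F. It draws on variation pooled over genes and is not the measured spread of a gene between libraries. The 20 gene lists were fixed beforehand and tested by camera (limma 3.58.1) with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. The estimated correlation rests on 1 residual degree of freedom. With it, immediate early genes in papilla-like cells, 20 of 20 above 0, reached an unadjusted camera p of 0.0773. A list that it does not call is therefore not evidence against a change. The preset correlation of 0.01 takes list members to vary nearly independently, and its p-values are too small where they do not. DESeq2 1.42.0 was the alternative test. Agreement of the 2 pairs was described over genes with at least 50 UMIs.

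Genes to name were chosen by a rule fixed beforehand. In each comparison it took the 10 higher and 10 lower genes with at least 50 UMIs, at least 2-fold in both pairs with intervals excluding 1, that had the largest smaller change; the 5 higher and 5 lower in the 18-month pair alone with the interval farthest from 1; up to 10 genes per direction that passed edgeR by adjusted p; and any list member. Sex-linked, mitochondrial, ribosomal and haemoglobin genes and unnamed gene models were exceptions, and Xist is given as a check of the samples only. The keratin genes of the unnamed cluster fall outside the rule and were chosen after their values were seen. Some genes that the rule allows are not reported here. The listed genes Trdc, Trac, Trbc2 and Cebpd are not in the files.

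Chosen after the results were seen were the edgeR test of cells per class, the fits within a shared cluster, those without clusters 18 and 19, the count of calls passing in other settings, the marker medians within classes, the size limits for lists that moved in opposite directions, and the genes plotted. Clustering settings, filters, doublets, chemistry, the age coding and the place of the 12-month library were varied as planned; the design text counts that library with the young ones while its file is named aged. On simulated data the ratio intervals held the true ratio for 95.2% of 12899 genes. With 200 genes changed, edgeR found 51 of 67 at 2-fold and 64 of 67 at 4-fold in data shaped like the dermal sheath-like class, and 11 of 67 and 60 of 67 in data shaped like all kept cells. The intervals were checked on Poisson draws. For edgeR every gene had the same dispersion and each changed gene the same fold in both pairs. These figures therefore check the code and do not give the power in the real libraries. Plots were drawn with matplotlib 3.10.9.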

Results

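Single cells of the mouse hair follicle mesenchyme, the connective tissue cells in and around the follicle, were profiled at 2, 12 and 18 months of age. The study's title names dysfunction of mesenchymal progenitors in age-related hair loss as its subject. Mice on the C57BL/6J background carried a tamoxifen-inducible Cre under the α-smooth muscle actin promoter and a fluorescent reporter, and were given tamoxifen on postnatal days 3 and 4, which marks cells that make smooth muscle actin at that time, those of the dermal sheath included, and their descendants. Dermal cells of back skin were sorted into a gate that was positive for the reporter and a gate that was positive for Cd26, each also positive for Itga9 or Cd200, and 5000 cells of each gate were mixed. There were 4 libraries. A 2-month and an 18-month library were made with 10x version 2 chemistry from mice labelled YFP, and another 2-month library and a 12-month library with version 3 chemistry from mice labelled TdTomato. Sex went with chemistry, since Xist was at 0 and 0.104 CPM in the version 2 libraries and at 830 and 849 CPM in the version 3 libraries. The reporter went with chemistry by the labels, but the eYFP entry was at 1166 and 2942 CPM in the libraries labelled YFP and at 1628 and 1633 CPM in those labelled TdTomato, so the reporter of the version 3 libraries is uncertain. Within each pair age was compared at the same chemistry, sex and labelled reporter. Hair cycle stage was not stated in the labels used here. The labels give 2 mice per sample without saying whether they were pooled. Nothing says that libraries of an age came from separate litters or days. The p-values therefore speak for these libraries only. They draw on variation pooled over genes beside the spread between libraries.

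The deposited UMI counts totalled 17831300 in the 2-month and 21083193 in the 18-month version 2 library, and 77032628 in the 2-month and 55396394 in the 12-month version 3 library. After filtering, 1677, 2431, 5388 and 3964 cells were kept in that order, with a median of 6253, 6594, 11926 and 11793 UMIs per cell. The version 2 files held 1906 barcodes at 2 months and 2727 at 18 months, against 2604 and 3776 recovered cells in the sample labels. The labels, like the files, give fewer cells at 2 than at 18 months. The design text gives 2707 cells for its sample 1 and 1906 for its sample 2, so that 1906 stands there for the second sample and is found here in the file of the 2-month sample. The version 3 files held 7023 and 5474 barcodes, against 6998 and 5415 in both descriptions. Every direction given for the 18-month pair, every test across the 4 libraries and every comparison of the 2 pairs rests on the files being assigned as deposited.

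The first question was which cells the sorted mesenchyme held at each age. Dermal papilla-like cells, the signalling cells at the base of the follicle, made up 32.9% of the 2-month and 19.9% of the 18-month library in version 2 (95% Clopper-Pearson intervals 30.6% to 35.2% and 18.3% to 21.5%), and 21.7% of the 2-month and 13.1% of the 12-month library in version 3 (20.6% to 22.8% and 12.1% to 14.2%). Arrector pili-like cells, the smooth muscle that raises the hair, were 3.88% (3.00% to 4.91%) at 2 months and 0.699% (0.408% to 1.12%) at 18 months. In version 3 they were 8.52% (7.79% to 9.30%) at 2 months, and at 12 months 2 cells were found, 0.0505% (0.00611% to 0.182%). Macrophage and dendritic-like cells were 6.20% at 2 months and 15.4% at 18 months in version 2, and in version 3 12.5% at 2 months and 6.47 percentage points more at 12 months. Dermal sheath-like cells, the contractile layer around the follicle that holds its dermal stem cells, were 11.9% at 2 months and 15.7% at 18 months, and 40.1% at 2 months and 41.5% at 12 months. Pericyte-like cells were 13.0% and 10.3% in version 2 and 0.538% and 0.277% in version 3, keratinocyte-like cells 14.5% and 4.61%, and 4.45% and 4.16%. Endothelium-like cells were 0.596% and 1.23%, and 2.93% and 1.24%, and cycling cells 2.86% and 1.56%, and 1.19% and 1.61%.

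Dermal fibroblast-like cells were 13.2% at 2 months and 29.2% at 18 months, and 6.96% at 2 months and 17.7% at 12 months, but this depended on how clusters were named. With the 3 fibroblast marker lists kept apart the differences were -0.197 and -2.17 percentage points, and with each library clustered alone the version 3 difference was -9.99 points. The dermal sheath-like difference at 18 months, 3.75 points, was -10.4 points with a looser cell filter. At 12 months it was 1.42 points, but 18.9 at resolution 1, 17.3 with each library clustered alone and 11.7 with the looser filter. The lower papilla-like and arrector pili-like shares and the higher macrophage and dendritic-like share kept their direction under all settings run for shares. The intervals cover counting error only, and the sort sets the shares in part. Across the 4 libraries, with chemistry as a covariate, an edgeR test of cells per class that was added after the shares were seen called 0 of 10 classes. At an unadjusted p under 0.05 were 2 of them, dermal fibroblast-like (log2 fold 1.25 ± 0.15, adjusted p = 0.190) and dermal papilla-like (-0.72 ± 0.12, adjusted p = 0.190).

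**Figure D1:**
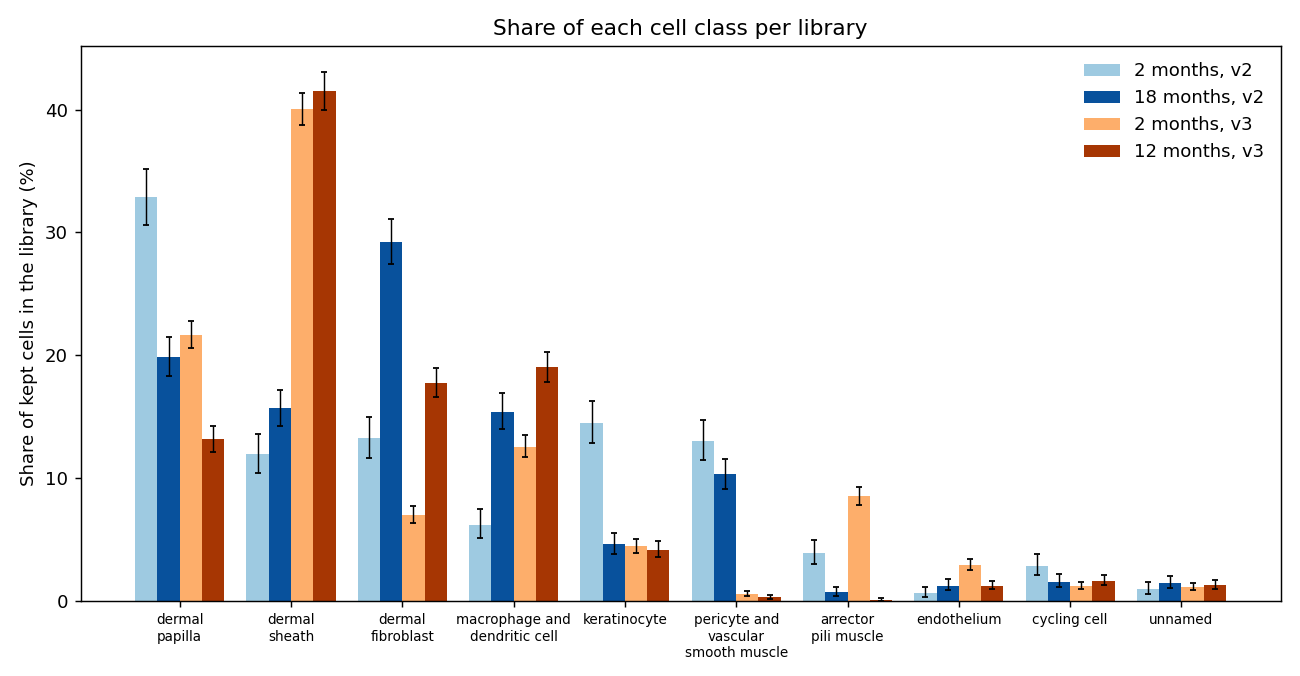
Share of kept cells (%, vertical axis) in each cell class for the 4 libraries. Bars are shares of 1 library each and error bars are 95% Clopper-Pearson intervals, which cover counting error only. The dermal papilla-like bar is lower in the older library of both pairs (32.9% and 19.9%, 21.7% and 13.1%), and the arrector pili-like bar is near 0 at 12 months (0.0505%).

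The only comparison with 2 libraries on each side set the 12-month and 18-month libraries against both 2-month libraries, with chemistry as a covariate. Over all kept cells, genes that were higher at the older age in both pairs included Cyp2f2, a cytochrome P450, at 21.6-fold (95% Poisson interval 16.4 to 29.0) in version 2 and 18.3-fold (16.0 to 21.1) in version 3, and Mmp3, a matrix metalloproteinase, at 9.65-fold and 7.38-fold. Pla2g2e, a secreted phospholipase, was 7.92-fold and 12.9-fold higher. Genes of pigment cells were lower. The ratio of Tyr, which encodes tyrosinase, was 0.0126 (0.00151 to 0.0464) in version 2 and 0.0213 (0.000531 to 0.123) in version 3, from 2 and 1 UMIs in the older libraries, and Tyrp1 was 137-fold and 25.3-fold lower. None of these passed the test across the 4 libraries: edgeR's quasi-likelihood test called 0 of 15454 genes, with 1741 at an unadjusted p under 0.05, while DESeq2 called 379. Of the gene lists fixed beforehand, proteases and their inhibitors had 23 of 24 members above 0 (median log2 fold 0.80) and 10 higher adjusted over the list alone, and fibrillar collagen and interstitial matrix 25 of 26 above 0 (median 0.64) with 5 higher adjusted over the list alone. Both passed camera with a preset correlation, at adjusted p = 2.75e-10 and 2.31e-09, and not with an estimated one, at adjusted p = 0.835 and 0.882. The estimated correlation rests on 1 residual degree of freedom, so that failure decides nothing. The preset p-values hold only if members vary nearly independently, while the estimates were 0.22 for proteases and 0.70 for matrix genes. Neither version of the test therefore settles a change of these lists. Markers of lower dermis and fascia fibroblasts moved with these lists, with a median log2 ratio of 1.11 at 18 and 0.42 at 12 months, so these values mix changes within cells with changes in shares.

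Dermal sheath-like cells showed a coordinated rise of immediate early genes, which are transcribed within minutes of a stimulus. Of 20 members measured, 19 rose and none fell, with a median log2 fold of 1.30, and the count was the same adjusted over the list alone. Socs3, a feedback inhibitor of cytokine signalling, rose by a log2 fold of 2.39 ± 0.14 (SE, 2 against 2 libraries, edgeR adjusted p = 4.93e-23), the AP-1 subunit Fosb by 1.83 ± 0.14 and Fos by 1.60 ± 0.13. The SE draws on variation pooled over genes. Within cluster 4, which all libraries share, the log2 ratio of Socs3 was 4.06 at 18 and 1.84 at 12 months, a wider gap than the SE shows. Among senescence-associated genes 5 of 17 rose and 2 fell, and 7 and 2 adjusted over the list alone. Cdkn2a encodes the cell cycle inhibitor p16 and the protein ARF, which counts per gene do not tell apart. Cdkn2a rose by 2.14 ± 0.22 (edgeR adjusted p = 7.63e-12), being 3.76-fold higher at 18 months (1.95 to 8.14) and 4.46-fold at 12 months (3.57 to 5.62). Cdkn1a, which encodes p21, rose by 1.32 ± 0.14. Igfbp3 (-0.60 ± 0.14) and Gdf15 (-1.44 ± 0.43) fell. Complement genes rose in 3 of 7 cases, among them the C1 protease gene C1s1 (1.43 ± 0.14), and no member fell.

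Chemokine and cytokine genes rose in 5 of 15 cases in these cells, including Ccl2 (1.25 ± 0.16), Cxcl12 (1.04 ± 0.14) and Il1b (1.89 ± 0.32), and 1 fell, Il33 (-0.60 ± 0.16). Ctla2a, which encodes a cysteine protease inhibitor, rose by 4.08 ± 0.24. It rose from 0 UMIs at 2 months in version 2 (at least 20.6-fold higher at 18 months, against a floor of 3 UMIs) and 14.5-fold at 12 months. Has1, a hyaluronan synthase, rose by 2.25 ± 0.22. Ctla2a is among the top genes of the fibroblast-like cluster 6 and Has1 of cluster 14, and both clusters held more cells in the older libraries. How far RNA of fibroblast-like cells adds to these values was not tested. Interferon-related genes were mainly lower, with Isg15 (-0.86 ± 0.16) and Oasl2 (-0.91 ± 0.23) among 4 that fell and Irf1 (1.15 ± 0.14) the 1 that rose. In the hedgehog list Hhip fell (-1.07 ± 0.32) and 8 of 9 members lay below 0, beside a median log2 ratio of -0.43 at 18 and -0.18 at 12 months for dermal papilla markers, of which Hhip is one. In the heat shock list 4 of 12 rose, among them Hspa5 (0.71 ± 0.12). Of 26 structural matrix genes 9 lay above 0 and 17 below. Called were 2 higher (Dcn, Lum) and 4 lower (Eln, Col6a2, Col6a3, Fbln2), and adjusted over the list alone 3 and 9. Dcn and Lum are also among the top genes of the fibroblast-like cluster 14. Keratinocyte genes such as Krtdap (-1.64 ± 0.14) and the arrector pili marker Des (-4.95 ± 0.36) fell as well. Keratinocyte markers as a set were lower in these cells, at a median log2 ratio of -1.14 at 18 and -0.46 at 12 months. Macrophage markers stood at 1.40 and -0.46, which moved with Il1b and the chemokines at 18 months only. That list holds macrophage and dendritic cell genes together, and Il1b leads the dendritic-type cluster 1. In version 3 cluster 1 held 109 cells at 2 and 311 at 12 months, and the macrophage-type cluster 12 held 567 and 443. The median therefore does not tell whether RNA of dendritic-type cells adds to Il1b at 12 months. Within cluster 4, which all libraries share, the chemokine and cytokine median was 1.47 at 18 and -0.04 at 12 months, and that of heat shock genes 0.63 and -0.16. Interferon-related genes stood there at -0.24 and 0.10, and complement genes at 0.13 and 0.84. Senescence-associated genes, at 0.68 and 0.20, and hedgehog genes, at -0.53 and -0.15, had the same sign in both pairs.

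In all, 357 genes rose and 199 fell of those tested in dermal sheath-like cells. DESeq2 called 96. Among cells with at least 1000 genes edgeR called 0, with 719 at an unadjusted p under 0.05. With the 12-month library counted as young, as in the design text, it called 0 in this class, with 627 unadjusted, and without chemistry as a covariate 0, with 172. Preset-correlation camera called 8 of 20 lists, including immediate early (adjusted p = 5.73e-16), and none was called with an estimated correlation (adjusted p = 0.574 for immediate early). Different clusters held the class: cluster 8 held 1741 of 2158 such cells at 2 months in version 3 and cluster 21 held 1327 of 1644 at 12 months, while cluster 4 was shared by all libraries and gave 129 calls.

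Dermal papilla-like cells showed higher immediate early and chemokine genes at the older ages. In the immediate early list 15 of 20 members rose (20 adjusted over the list alone), with a median log2 fold of 1.31, and all 20 were higher in both pairs. Fosb rose by 1.82 ± 0.19 (edgeR adjusted p = 0.00118) and Socs3 by 1.67 ± 0.19 (adjusted p = 0.00179). Chemokine and cytokine genes rose in 6 of 13 cases (8 adjusted over the list alone) and none fell. Ccl7, a monocyte-attracting chemokine, rose by 3.00 ± 0.28 (adjusted p = 0.000858), being 12.8-fold higher at 18 months (5.61 to 35.9) and 6.47-fold at 12 months (4.98 to 8.49). Ccl2 (2.17 ± 0.35), Cxcl1 (1.78 ± 0.30), Il1b (2.07 ± 0.41) and Cxcl14 (1.13 ± 0.20) also rose, and of 7 complement genes C1s1 did (1.39 ± 0.19). Macrophage markers in these cells stood at a median log2 ratio of 1.85 at 18 and -0.43 at 12 months. The list mixes macrophage and dendritic cell genes, so its median does not tell whether RNA of dendritic-type cells adds to Il1b. In the senescence-associated list 4 of 17 members rose and 1 fell, and 8 and 1 adjusted over the list alone. Cdkn1a (1.36 ± 0.27) rose, whereas Cdkn2a, at 1.19 ± 0.30, did not pass (adjusted p = 0.0923).

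Matrix and growth factor genes changed in the papilla-like cells too. Tenascin C, Tnc (2.03 ± 0.37), and decorin, Dcn (1.41 ± 0.21), were among 3 of 26 matrix genes that rose. Tnc is among the top genes of the fibroblast-like cluster 6 and Dcn of cluster 14. How far RNA of fibroblast-like cells adds to these values was not tested. The matrix list's median log2 ratio was -0.03 at 18 and 0.68 at 12 months, beside dermal sheath markers at -0.23 and 0.46 in these cells. The growth factors Igf1 (1.04 ± 0.20) and Igf2 (1.86 ± 0.32) were among 4 of 21 in their list, where Igfbp5 fell (-1.07 ± 0.21). The metallothionein genes Mt1 (1.01 ± 0.22) and Mt2 (1.64 ± 0.23) rose. The cyclin gene Ccnd2 fell by 2.93 on the log2 scale (SE 0.30, edgeR adjusted p = 0.00118), being 4.78-fold lower at 18 and 11.7-fold lower at 12 months. Lypd1 (-1.45 ± 0.20) and Apela, which encodes a peptide ligand (-1.33 ± 0.20), fell. Krtdap (-1.74 ± 0.20) and other keratinocyte genes fell beside a keratinocyte marker median of -1.45 at 18 and -0.65 at 12 months. The papilla markers Corin (-0.43 ± 0.18, adjusted p = 0.409) and Sox2 (-0.62 ± 0.23, adjusted p = 0.326) did not pass. The papilla marker list had a median log2 ratio of -0.02 at 18 months, and of -0.69 at 12 months with 17 of 20 members lower.

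Of 151 genes called in papilla-like cells, 107 rose and 44 fell, and 54 of the 151 passed in each of 7 other settings that kept the age coding and chemistry. With the 12-month library counted as young edgeR called 0, with 329 at an unadjusted p under 0.05, and without chemistry 0, with 92. DESeq2 called 61. Preset-correlation camera called 11 lists, including immediate early (adjusted p = 1.84e-22), and none with an estimated correlation (adjusted p = 0.733 for immediate early). The class was held mostly by cluster 0 at 2 months and cluster 20 at 18 months in version 2, and by cluster 15 in both version 3 libraries.

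**Figure D2:**
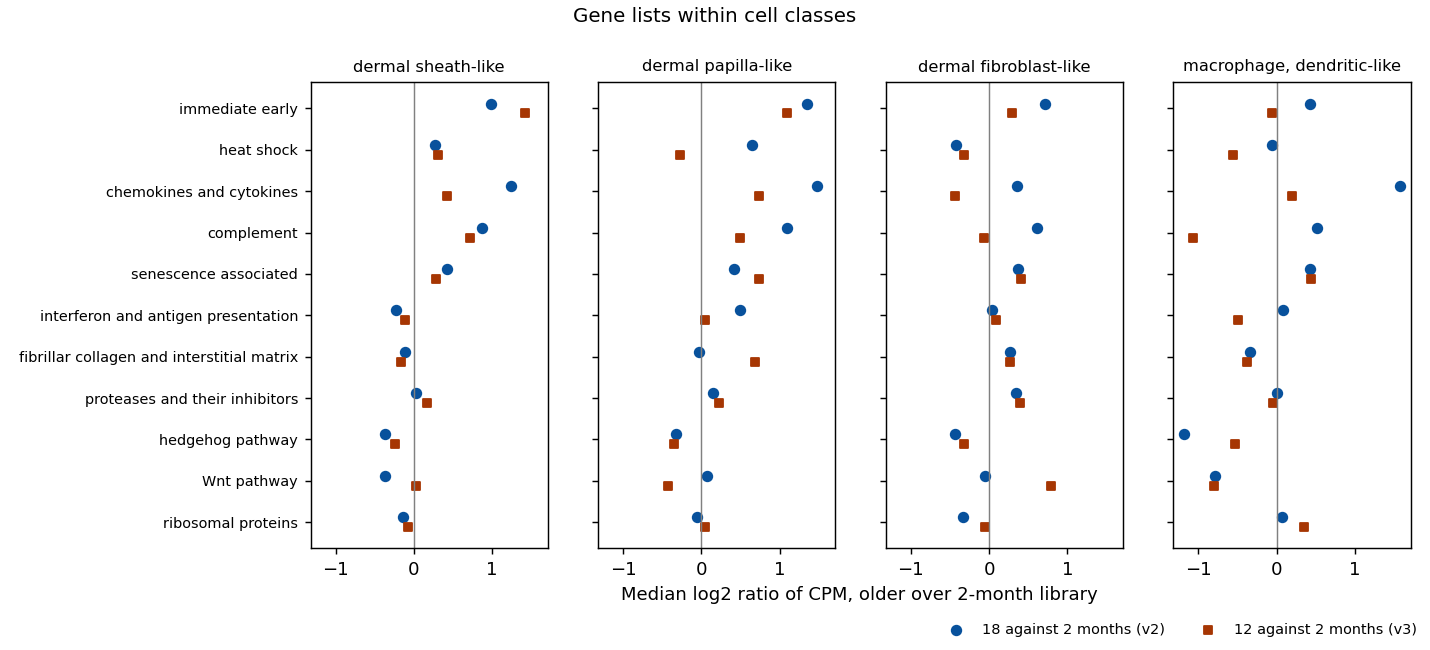
Median log2 ratio of CPM (horizontal axis, older over 2-month library) over the members of 11 gene lists (vertical axis) in 4 cell classes, with circles for 18 against 2 months in version 2 and squares for 12 against 2 months in version 3. Each point compares 1 library with 1 library. Immediate early genes lie near 1 or above in both pairs in dermal sheath-like (0.98 and 1.42) and dermal papilla-like cells (1.35 and 1.09), and at 0.42 and -0.06 in macrophage and dendritic-like cells, where scaling by the trimmed mean of M-values gives 0.72 and 0.24.

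Dermal fibroblast-like cells had 7 genes that rose and 4 that fell. Cdkn2a rose by 3.62 ± 0.23 (edgeR adjusted p = 0.0310), being 14.0-fold higher at 18 months (9.08 to 22.6) and 9.61-fold at 12 months (5.73 to 17.4). Ctla2a rose by 4.06 ± 0.17 (adjusted p = 0.0109), Cyp2f2 by 3.01 ± 0.16, Igfbp2 by 2.26 ± 0.17 and Mmp3 by 1.93 ± 0.16. Gpha2, a glycoprotein hormone subunit gene (2.83 ± 0.21), and Gpnmb, a transmembrane glycoprotein gene (2.07 ± 0.17), completed those that rose. The sphingomyelinase gene Smpd3 (-5.17 ± 0.24), the chemokine genes Cxcl13 (-3.31 ± 0.23) and Cxcl1 (-1.88 ± 0.16) and the interferon-induced Ifi27l2a (-2.54 ± 0.18) fell. Adjusted over the list alone, 6 of 20 immediate early genes were higher, as were 7 of 18 senescence-associated genes, with 2 lower.

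The fibroblast-like class pooled clusters 6, 7, 14, 18 and 19, which the libraries filled differently. Cluster 14, whose top genes include Cyp2f2, Mmp3 and Gpnmb, held 25 of 222 cells of the class at 2 and 224 of 711 at 18 months, and 45 of 375 at 2 and 326 of 703 at 12 months. Cluster 6, whose top genes include Ctla2a and Gpnmb, held 85, 200, 13 and 156 of the same totals. Cluster 19, with 54 of its 62 cells in the 2-month version 3 library, carried macrophage genes beside fibroblast genes, with Cd74 at 4291 CPM there against 26.9 CPM in cluster 7 of the same library. Macrophage markers in the class stood at a median log2 ratio of -0.20 at 18 and -4.03 at 12 months, and keratinocyte markers at -1.90 and -0.67. Without cluster 19 the test called 313 genes, among them all 11, and without clusters 18 and 19 it called 318, among them 9, with Cxcl1 at 1.31 ± 0.63 and not called and Smpd3 too low to test. Smpd3 was at -3.53 ± 0.54 without cluster 19, and without both clusters Cxcl13 was at -1.85 ± 0.34 and Ifi27l2a at -1.84 ± 0.22. Without cluster 19 macrophage and dendritic cell markers turned round, with 5 of 12 called higher and none lower, among them Cd74 (2.39 ± 0.42, against -2.01 with cluster 19 kept, not called). The direction of chemokines and cytokines depended on these clusters: with all clusters 2 of 20 fell and none rose, 6 rose and 3 fell without cluster 19, and 9 rose and 1 fell without clusters 18 and 19. Adjusted over the list alone, 7 were higher and 5 lower with all clusters. Without both, Cxcl2 (3.05 ± 0.31, against -1.69 with all clusters), Il6 (2.26 ± 0.24) and Ccl7 (1.94 ± 0.24) rose.

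The edgeR count in fibroblast-like cells was 0 with each library clustered alone, with 1819 at an unadjusted p under 0.05, and 652 with doublets kept, and DESeq2 called 110. With the 12-month library counted as young edgeR called 0, with 626 unadjusted, and without chemistry 0, with 477. Camera called 9 lists with a preset correlation, including immediate early and proteases and their inhibitors (adjusted p = 1.03e-05 for each), and none with an estimated one (adjusted p = 0.665 for each).

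Macrophage and dendritic-like cells had 127 genes that rose and 25 that fell. Cd207, the Langerhans cell gene for langerin, rose by 2.43 ± 0.25 (edgeR adjusted p = 0.0122), as did the cystine transporter gene Slc7a11 (2.95 ± 0.30), the nuclear receptor gene Nr4a3 (2.36 ± 0.24), Plet1 (2.13 ± 0.25) and the chemokine gene Ccl5 (2.08 ± 0.26). In the chemokine and cytokine list 3 of 20 rose (7 adjusted over the list alone) and none fell: Il1b (1.69 ± 0.25), Cxcl13 (2.93 ± 0.34) and Cxcl16. Bmp2 (-2.45 ± 0.31), Fst (-1.72 ± 0.25), Hhip (-1.56 ± 0.23) and Igfbp5 (-1.87 ± 0.26) fell, beside a median log2 ratio of -0.99 at 18 and -1.12 at 12 months for dermal papilla markers in these cells. The dendritic-type cluster 1 held 85 of 104 such cells at 2 months and 298 of 374 at 18 months, and 109 of 676 at 2 months and 311 of 754 at 12 months, the rest being the macrophage-type cluster 12. Within cluster 1 alone edgeR called 0 genes, with 1586 at an unadjusted p under 0.05, and among cells with at least 1000 genes it called 0, with 1387. DESeq2 called 114 over the class. With the 12-month library counted as young edgeR called 0, with 580 unadjusted, and without chemistry 0, with 162. Camera called 8 lists with a preset and none with an estimated correlation (adjusted p = 0.716 for senescence associated), and fry called senescence associated alone (adjusted p = 0.00483). That list's median log2 ratio was 0.43 at 18 and 0.44 at 12 months over the class, and -0.21 and 0.08 within cluster 1. By TMM the cluster 1 medians were 0.20 and 0.42, so the sign at 18 months turns with scaling. The class medians are likewise higher by TMM.

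Keratinocyte-like cells gave 0 calls of 10573 genes by edgeR, with 453 at an unadjusted p under 0.05 and 8 calls by DESeq2. Lum, which encodes a matrix proteoglycan, was 11.6-fold (6.50 to 22.2) and 10.0-fold (5.14 to 21.9) higher in the older libraries, beside lower dermis and fascia fibroblast markers at a median log2 ratio of 1.80 at 18 and 0.22 at 12 months in these cells. The barrier genes Sprr2e, at 4.55-fold and 24.6-fold, and Crct1, at 5.52-fold and 3.22-fold, were lower. Cluster 2 held 216 of the 243 such cells at 2 months in version 2 and cluster 16 most of those in the other libraries. The markers that named cluster 2 were Krt10, Krt1, Dsp, Perp and Sfn, while those of cluster 16 also included Krt14, Krt5 and Krt15. The 18-month pair thus compares differing kinds of keratinocyte-like cells, and its ratios and the lists called mix that difference with age. Camera called 6 lists with a preset correlation, including cell cycle (20 of 23 members above 0, adjusted p = 9.67e-05), and none with an estimated one (adjusted p = 0.964 for cell cycle).

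**Figure D3:**
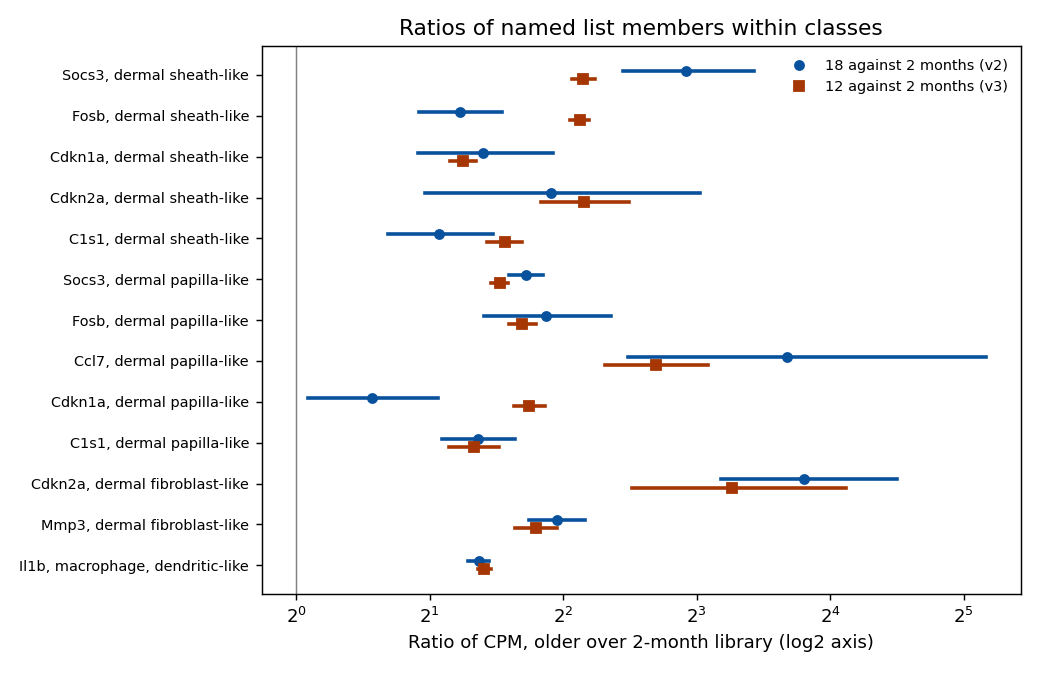
Ratio of CPM (horizontal log2 axis, older over 2-month library) for 13 list members within classes, chosen for the plot after their values were seen. Circles are 18 against 2 months in version 2, squares 12 against 2 months in version 3, and lines are 95% Poisson intervals that cover counting error only. Cdkn2a in dermal fibroblast-like cells lies at 14.0-fold and 9.61-fold.

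The last comparison asked how far the 2 pairs, which share no library, moved together. Across 15210 genes over all kept cells, the log2 ratios of the pairs had a Pearson r of 0.277 and a Spearman rho of 0.317, a description only, since genes are not independent replicates. At least 2-fold changes in both pairs were in the same direction for 302 higher and 227 lower genes and in opposite directions for 154. Pearson r was 0.245 in dermal sheath-like, 0.207 in dermal papilla-like, 0.241 in dermal fibroblast-like, 0.224 in macrophage and dendritic-like and 0.008 in keratinocyte-like cells. Genes that stood out at 18 months alone included the chemokine gene Ccl8 in papilla-like cells, 24.3-fold higher at 18 months (12.6 to 53.9) and 2.86-fold lower at 12 months; the median log2 ratio of macrophage markers in the class moved likewise, at 1.85 and -0.43. In macrophage and dendritic-like cells Ccl4 was 8.61-fold higher at 18 months (7.55 to 9.85) and 1.17-fold lower at 12 months, a sign that turns with scaling by the trimmed mean of M-values (log2 ratio 0.07).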

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

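The tests of explanations in this part, and the size limits used to pick the gene lists, were chosen after the results were seen; the correlation of the pairs and the shares without a mitochondrial limit that they draw on were planned. Some gene lists moved in opposite directions in the 2 pairs, with medians outside the middle 95% of random lists of like expression in both, and the difference between the pairs was not tested. In dermal fibroblast-like cells the median log2 ratio of chemokines and cytokines was 0.35 at 18 months and -0.44 at 12 months, and within cluster 7, which all libraries share, it was 0.01 and 0.61. In macrophage and dendritic-like cells that of complement genes was 0.52 and -1.07. The shared cluster 1 held 85 of these cells at 2 and 298 at 18 months, and 109 at 2 and 311 at 12 months. Within that cluster the median log2 ratio was 0.20 and -0.58 by CPM, and 0.60 and -0.24 by TMM. In keratinocyte-like cells it was 2.06 and -0.46 for fibrillar collagen and interstitial matrix, 2.89 and -0.36 for basement membrane, 1.16 and -0.51 for the Wnt pathway, -0.69 and 0.73 for adipogenic genes, and 1.24 and -0.68 for the contractile cytoskeleton, beside dermal sheath markers at 1.69 and -0.76, dermal papilla markers at 0.92 and -1.96 and upper dermis fibroblast markers at 1.21 and -0.22 in these cells. The keratinocyte-like cells came mostly from cluster 2 at 2 months in version 2 and from cluster 16 in the other libraries. The eYFP entry, which the comparisons did not use, had 1628 CPM in the 2-month and 1633 CPM in the 12-month library labelled TdTomato.

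Immediate early genes were higher in the older dermal sheath-like cells. The class is held by different clusters in different libraries, but within the shared cluster 4 the list's median log2 ratio was at least 1.15 in both pairs, which argues against that as the whole cause. A handling difference that raises these genes in every class alike is argued against in both pairs within shared clusters, where the median in cluster 4 exceeded that in the dendritic-type cluster 1 by 1.25 by CPM and 0.936 by TMM at 12 months (20 and 19 of 20 members higher), and by 1.36 and 0.941 at 18 months (18 and 16 of 20). Over whole classes, held by different clusters, the excess over macrophage and dendritic-like cells was 1.48 and 1.22 at 12 months and 0.56 and 0.27 at 18 months, the last too small to decide alone, and over keratinocyte-like cells 1.51 and 1.54, and 0.65 and 1.09. The fibroblast-like cluster 7, also shared by all libraries, had a median of 0.87 at 18 and 1.47 at 12 months by CPM. That of cluster 4 was 1.62 and 1.15, so the rise was not particular to sheath-like cells. In cluster 1 the median was 0.26 at 18 and -0.10 at 12 months by CPM, and 0.66 and 0.24 by TMM. The gap between clusters 4 and 1 therefore speaks only against an equal rise. A handling difference that raises these genes more weakly in cluster 1 than in sheath-like and fibroblast-like cells, or not at all there, is not argued against. A response to the 37 °C digestion that differs between cell types, hair cycle stage, and age itself remain open, as untested.

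Arrector pili-like cells were scarce in both older libraries. Placement of all such cells in other clusters is argued against by the marker genes over all kept cells, whose median log2 ratio was -0.82 or lower in both pairs. In at least 1 pair this fall was smaller than that of the share, so placement of a part of them elsewhere is not argued against. The marker Actg2 is also among the top genes of the sheath-like clusters 9 and 21. Without a mitochondrial limit the 2-month share was still at least 4.71 times the older share, which argues against removal by that filter. A difference in sorting or dissection cannot be told apart from age, because each age and chemistry has 1 library; of the arrector pili-like cells of the 2-month version 3 library, which is labelled TdTomato, 99.8% had a UMI of the eYFP entry after thinning to 3000 UMIs per cell, against 25.9% of its keratinocyte-like cells, which should lack a reporter. Loss of these cells with age may be considered only as an untested hypothesis.

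The cell numbers in the descriptions do not match the version 2 files. An exchange of the 2 files would place 1906 barcodes at 18 months, as the design text states for its sample 2, and 2727 at 2 months, near the stated 2707. The labels speak against an exchange of files: as deposited the files hold 73.2% and 72.2% of the labels' cells at 2 and 18 months, and exchanged they would hold 105% and 50.5%. The changes of the 2 pairs correlated across genes at r = 0.277, the sign that the deposited assignment gives if the older libraries share changes, but too weak to decide. The descriptions conflict, so an exchange cannot be told apart from a wrong number or order in the text.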

How the results depend on the processing

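The test of cells per class and the settings with marker lists unpooled, a single shared cluster and clusters 18 or 19 left out were chosen after the results were seen. Of 170 alternative values, 78 kept their direction and size or side of the threshold, 58 moved, 24 lost and 5 gained a call, and 5 reversed. Replicate numbers could not pair the libraries, because the age groups share fewer than 2 of them. The libraries are matched by chemistry instead, which the main model already has as a block. Leaving out a library leaves no residual degrees of freedom with chemistry in the model, and dermal sheath-like cells with doublets kept had 7 cells in the 2-month version 2 library, so neither gave a test. Depth limits the classes with few cells, and 1 residual degree of freedom limits every test. Except where stated, the cause of a change was not tested.

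Differences in share are in percentage points. For dermal papilla-like cells the difference at 18 months was -9.82 with each library clustered alone, and at 12 months -12.1 so clustered, -10.4 at resolution 1 and -10.6 with doublets kept. For dermal sheath-like cells at 18 months it was 0.829 at resolution 0.25, 1.22 at resolution 1, 1.27 with each library alone, 10.6 with doublets kept, and reversed to -10.4 in cells with at least 200 genes and no mitochondrial limit (the looser filter); at 12 months it was 18.9 at resolution 1, 17.3 with each library alone, 3.84 with doublets kept and 11.7 under the looser filter. For dermal fibroblast-like cells at 18 months it was 19.1 at resolution 0.25 and 18.7 at resolution 1, 11.9 with doublets kept, 27.7 under the looser filter and reversed to -0.197 with lists unpooled; at 12 months it was 12.2 at resolution 0.25 and 7.93 with doublets kept, and reversed to -9.99 with each library alone, -3.21 under the looser filter and -2.17 with lists unpooled. For macrophage and dendritic-like cells at 12 months it was 11.9 with each library alone and 4.39 under the looser filter.

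The edgeR test of cells per class called 0 of 10 classes with library totals and with TMM, with 2 and 1 at an unadjusted p under 0.05.

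With DESeq2 the counts of called genes were 379 over all kept cells, 110 in dermal fibroblast-like, 61 in dermal papilla-like, 96 in dermal sheath-like and 8 in keratinocyte-like cells. Without the filter on low counts they were 80 over all kept cells, 430 in fibroblast-like (217 higher, 213 lower), 411 in papilla-like, 153 in keratinocyte-like and 598 in macrophage and dendritic-like cells (429 higher, 169 lower). Without chemistry as a covariate, edgeR called 0 in fibroblast-like (477 at an unadjusted p under 0.05), papilla-like (92), sheath-like (172) and macrophage and dendritic-like cells (162). With the 12-month library counted as young it called 0 in those classes (626, 329, 627 and 580 unadjusted) and 121 in keratinocyte-like cells. With log2 age as a number it called 0 in fibroblast-like (1080 unadjusted), 58 in papilla-like and 44 in macrophage and dendritic-like cells. Resolution 0.25 gave 361 in fibroblast-like, 272 in sheath-like and 284 in macrophage and dendritic-like cells (190 higher, 94 lower), and resolution 1 102 in fibroblast-like cells. With each library clustered alone there were 0 in fibroblast-like, 416 in papilla-like, 272 in sheath-like and 675 in macrophage and dendritic-like cells (428 higher, 247 lower). Doublets kept gave 652 in fibroblast-like (329 higher, 323 lower) and 406 in papilla-like cells. Cells with at least 1000 genes gave 31 in fibroblast-like (13 higher, 18 lower), 281 in papilla-like, 0 in sheath-like and 0 in macrophage and dendritic-like cells. A single shared cluster, with fewer cells, gave 120 in fibroblast-like, 129 in sheath-like and 0 in macrophage and dendritic-like cells. Fibroblast-like cells without cluster 19 gave 313 and without clusters 18 and 19 gave 318 (258 higher, 60 lower).

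Of the genes called, 54 of 151 in papilla-like cells passed in each of 7 other settings. In the other classes a setting with 0 calls rules such a count out, and 201 of 556 in sheath-like (7 settings), 149 of 152 in macrophage and dendritic-like (8) and 11 of 11 in fibroblast-like cells (10) passed in at least 50% of settings. Settings that changed the age coding or left out chemistry were not counted. Camera with an estimated correlation called 0 lists in each of the 6 comparisons, and fry called 0 in all but macrophage and dendritic-like cells, where it called 1. The estimated correlation rests on 1 residual degree of freedom, so the lack of camera calls with it decides nothing. Calls with the preset correlation hold only if list members vary nearly independently. In keratinocyte-like cells 2 of 6 called lists had medians of that sign in each pair alone.

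Pearson r between the pairs at 20 UMIs or more was 0.2497 over all kept cells, 0.209 in fibroblast-like, 0.184 in papilla-like, 0.210 in sheath-like and 0.205 in macrophage and dendritic-like cells, and at 200 UMIs or more 0.318 over all kept cells, 0.231 in papilla-like and 0.282 in sheath-like cells. With TMM the median log2 ratio of all genes at 18 months was 0.0168 over all kept cells, 0.0264 in fibroblast-like, -0.0837 in keratinocyte-like and 0.0164 in macrophage and dendritic-like cells, and 0.00184 in the last at 12 months, since TMM centres it by construction.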

Other observations

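Pigment cell genes were low in both older libraries. Over all kept cells the melanocyte marker list had a median log2 ratio of -6.06 at 18 months and -3.47 at 12 months, and 5 of its 6 members were lower in both pairs. Dct, which encodes a melanin synthesis enzyme, was 222-fold and 8.11-fold lower, and Slc45a2, a melanosome transporter gene, had a ratio of 0.0161 (95% Poisson interval 0.0004 to 0.0938) at 18 months from 1 UMI and was at least 10.1-fold lower at 12 months against a floor of 3 UMIs. No cluster was named melanocyte-like, the sort did not select these cells, and the values are from 1 library per age and chemistry. Follicles make pigment only during growth, and the hair cycle stage of the skin was not stated in the labels used here.

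A cluster of 164 cells that no marker list named was led by the inner root sheath and hair shaft keratin genes Krt71, Krt25, Krt27 and Krt35. It held 16, 35, 62 and 51 cells of the 2-month and 18-month version 2 and the 2-month and 12-month version 3 libraries, which is 0.954%, 1.44%, 1.15% and 1.29% of kept cells. Endothelial markers over all kept cells had a median log2 ratio of 0.72 at 18 months and -1.32 at 12 months, and lymphatic endothelial markers 0.03 and -1.11.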
